A study of Secale cereale x Triticum turgidum subsp. durum with 39 samples.

How the data were processed

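Total RNA of triticale anthers, ovaries, stigmas and mature pollen was hybridised to the Affymetrix Wheat Genome Array, which reports each transcript by a probe set. The 39 arrays fell into 13 groups of 3 by the organ and stage in the labels, which call the replicates biological. Per the labels' protocols, TET samples were extracted with PicoPure and labelled with a kit that repeats the amplification cycle, UNM and BCP samples of all 3 organs were extracted with RNeasy, cleaned of DNA with InviTrap, and labelled with the 3' IVT Express kit, and TCP and MPG samples were extracted on CsCl and labelled with a kit of a single cycle. The deposited values are on a log2 scale and were made by the authors with RMA, per the submitters' processing notes; its version, and whether all arrays were processed together, are not given in the sources used here. RMA corrects background, forces arrays to a common distribution and summarises probes, so a sample with fewer abundant transcripts can have its dim probe sets lifted. The array was designed for wheat, so a transcript of rye origin may hybridise less well than its wheat counterpart.

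The table held 61290 probe sets. The 86 bacterial, spike-in and tag controls were left out, and the 61204 remaining, wheat maintenance controls included, were tested with no filter on dim probe sets. Tests used limma 3.58.1 in R 4.3.3: lmFit with a mean for each of the 13 groups over all 39 arrays, contrasts between group means, and eBayes, with 26 residual and 7.5 prior degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1 either way; every adjusted p given is of this kind, over the 61204 probe sets of its comparison. Levels are means of log2 values with the SD over 3 arrays, and fold differences are 2 to the power of the log2 difference. Organ-preferential and pollen-associated sets are intersections of calls. A depth in reads does not exist for arrays; the number of arrays limits the precision.

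Gene names came from a platform annotation of 2007, which paired 1273 of the probe sets with 771 symbols, none with several, and left 59931 without a symbol. Of the symbols, 758 were locus numbers without a description and were not used. That left 13 genes, to which the names of the array's maintenance controls added 8, so 21 genes could be named. By the rule fixed before the data were examined, the text may name called genes whose compared groups do not overlap in any array (at no stage, in a mean of 4 stages) and called members of the fixed lists, at most 10 per direction, and leaves some of them out, and otherwise at most 2 probe sets per direction; a gene is represented by the probe set with the highest mean over all arrays. Of 18 gene lists fixed before the data were examined (meiosis, tapetum, pollen wall, starch, photosynthesis, cell cycle, MADS-box, defence, lipid transfer, ribosomal, dehydrin, heat shock, seed storage, peroxidase, cytoskeleton, cell expansion, hormone and transport genes), 3 had a named member, the largest had 2 (actin and TUBA), and none reached the minimum of 5, so the planned list tests could not be run.

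The test was checked on simulated arrays in which 200 probe sets were changed. Each probe set had its real overall mean, the same in every group, and independent normal noise of its residual SD. Apart from those 200 the simulation holds no group differences, unlike the data. It checks the method and does not give error rates of the real comparisons. For anther UNM to BCP it recovered 94% at a log2 size of 1.5, 94% at 2 and 98.5% at 3, with 2 false calls among the unchanged of 61204. For anther against ovary over 4 stages and for mature pollen against anther TCP it recovered 100% at each size with 0 false calls at the 2-fold minimum, and without that minimum 5 and 11 false calls at an adjusted p under 0.05.

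Replicate numbers in the labels were checked for pairing through the correlation of deviations from group means in 22 pairs of groups. Only for anther and stigma at BCP was every correlation over 0.1 (0.261, 0.104 and 0.129), so pairing was read as possible there alone. The main fit used no pairing, and the replicate block was run on all comparisons as an alternative. Alternatives fixed before the data were examined were 2 other scalings (the median of the brighter 50% of probe sets, or the mean of the hybridisation controls, set equal on all arrays), a filter on dim probe sets, a fit on the compared groups alone, a variance trend with robust moderation, array weights, a replicate block, a threshold of 0.01, no minimum fold, and leaving out each array. Those added after seeing the data were the mean of UNM and BCP alone and a minimum mean of 8.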

Results

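RNA abundance was measured on 39 wheat arrays hybridised with RNA of triticale, the hybrid cereal crop of wheat and rye, cultivar Alta. Anthers (the pollen-bearing organs), ovaries and stigmas (the pollen-receiving surface of the pistil) were sampled at 4 stages named after the pollen inside the anthers: tetrad (TET), uninucleate microspore (UNM), bicellular pollen (BCP) and tricellular pollen (TCP). Mature pollen grains (MPG) formed the last of the 13 groups, and each group held 3 biological replicates. Values were log2 signals of 61204 probe sets and ran from 1.95 to 15.02. The number of arrays limits the precision, since each group mean rests on 3 of them. Means under 6 are called dim here, and a fold against a dim mean is a fold of signal, not a measured ratio of transcripts. Replicates of a group correlated with r of 0.978 to 0.996 across probe sets, each of the 39 arrays correlated most strongly with an array of its own group, and no 2 arrays were identical.

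The extraction and labelling kits changed with the stage. TET samples shared one set of kits, UNM and BCP samples another, and TCP and MPG samples another again. Comparisons between organs within a stage, the step from UNM to BCP, and MPG against the TCP organs were therefore made within matched kits. The poly-A control transcripts differed even so: their mean was 9.02 in MPG and 8.61 in ovary TCP against 5.90 in anther TCP and 5.85 in stigma TCP, and it went from 6.12 at UNM to 6.93 at BCP in anthers, from 5.14 to 7.11 in ovaries and from 5.46 to 7.02 in stigmas. At the steps from TET to UNM and from BCP to TCP, stage and kit could not be told apart.

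Anther TCP and pollen arrays stood apart from all other groups. The first principal component held 45.9% of the variance, with mean scores of 269 for anther TCP and 344.5 for MPG, against 40.1 for anther BCP, 5.1 for stigma TCP and -59.3 for ovary TCP. The next components held 15% and 13.1%. The share of probe sets with a signal of at least 8 was 9.49% ± 0.18 (SD, n = 3) in MPG and 13.07% ± 0.40 (SD, n = 3) in anther TCP, against 15.94% ± 0.42 (SD, n = 3) in ovary TCP.

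**Figure D1:**
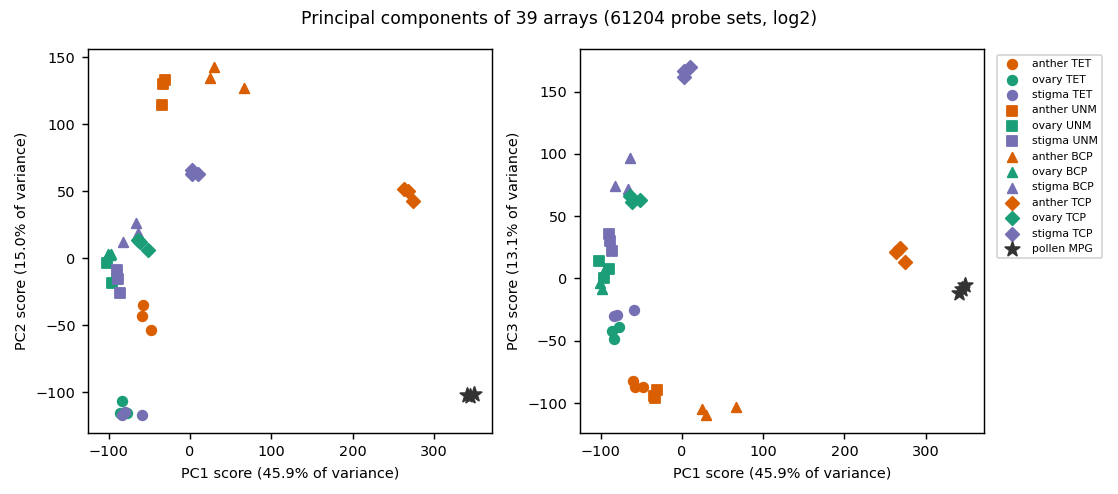
Principal component scores of the 39 arrays, with PC1 against PC2 on the left and PC1 against PC3 on the right. Each point is an array, colour marks the organ and shape the stage; anther TCP (mean PC1 score 269) and MPG (344.5) lie to the right of every other group, and stigma TCP (5.1) lies to the right of ovary TCP (-59.3).

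Averaged over the 4 stages, actin was 5.9-fold higher in anthers than in ovaries (log2 difference 2.56, SE 0.09, adjusted p = 1.7e-22), with means of 8.86 and 6.30, and 4.34-fold higher than in stigmas. FBP, a fructose bisphosphatase, was 3.67-fold higher than in ovaries (1.88, SE 0.10) and 2.81-fold higher than in stigmas. CAT1, a catalase, was 4.94-fold higher than in stigmas (2.31, SE 0.16). Lower in anthers was XTH, a xyloglucan endotransglucosylase/hydrolase that acts on cell wall xyloglucan, by 8.16-fold against ovaries (-3.03, SE 0.10, adjusted p = 2.3e-23) and 17.7-fold against stigmas (-4.15, SE 0.10, adjusted p = 3.3e-27). XTH was dim in anthers and CAT1 in stigmas. Actin is given here and below by the M probe set of the array's actin control, and stands only for the transcripts that probe set detects. The actin mean was carried by BCP and TCP: at TET and UNM actin was at 5.96 and 5.95 in anthers, 6.33 and 6.19 in ovaries, and 6.37 and 6.64 in stigmas. FBP was lower in anthers than in stigmas at TCP (7.35 against 8.87). The control transcript CYP86-TA was 4.03-fold lower than in stigmas at its 3' probe set alone. Its 5' and M probe sets were called in none of the comparisons for which CYP86-TA is given here.

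Across all probe sets, 3127 were called higher and 4407 lower in anthers than in ovaries, and 3390 higher and 3578 lower than in stigmas. Stigmas and ovaries differed at fewer: 945 were higher and 1526 lower in stigmas. In that comparison XTH was 2.17-fold higher in stigmas (1.12, SE 0.10, adjusted p = 6.9e-11) and petC, the Rieske iron-sulphur protein of the chloroplast cytochrome b6f complex, 3.65-fold lower (-1.87, SE 0.11, adjusted p = 1.9e-16), and the remaining 19 of the 21 named genes did not pass the test. XTH was higher in stigmas at BCP and TCP only, with 7.60 and 9.01 in stigmas against 7.79 and 9.17 in ovaries at TET and UNM. With arrays set equal on the hybridisation controls the split became 2282 higher and 6963 lower for anther against ovary, 2244 and 7238 for anther against stigma, and 1176 and 1242 for stigma against ovary. With scaling on the brighter probe sets the majority turned for anthers, to 3742 and 3564 against ovaries and 3664 and 3195 against stigmas.

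Averaged over UNM and BCP alone, a choice made after seeing the data, FBP was further apart between anthers and stigmas (2.82). Actin was less far apart (1.64 against ovaries and 1.03 against stigmas), and the call of XTH between stigmas and ovaries ended (0.74).

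Organ-preferential sets were built from probe sets called higher in an organ than in both others in the mean of the 4 stages. They held 2533 probe sets for anthers, 835 for ovaries and 594 for stigmas. In anthers the median level of the set rose from 5.71 at TET to 7.36 at UNM, 8.23 at BCP and 8.56 at TCP, while the same probe sets stayed between 4.94 and 5.25 in ovaries. The stigma set had medians of 6.61, 8.15, 9.09 and 9.90 in stigmas at the 4 stages, and the ovary set 8.55, 8.75, 8.74 and 8.37 in ovaries, where the other organs fell away instead: anthers went from 6.99 at TET to 4.98 at TCP and stigmas from 7.58 to 5.12. The excess over the next organ was largest at TCP for 1032 anther, 570 ovary and 343 stigma probe sets, and at TET for 212, 28 and 27. The medians over stages are descriptive, and cross the kit changes; the sets were chosen on these same arrays.

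At the tetrad stage, anthers already held more of the G-6-PDH control transcript, which is named for the entry enzyme of the pentose phosphate pathway, than ovaries (7.25-fold, log2 difference 2.86, SE 0.21, adjusted p = 5.5e-13) and stigmas (6.02-fold). Higher in anthers at TET were also petC (4.68-fold against ovaries, 9.03-fold against stigmas), CAT1 (3.62-fold and 4.37-fold), FBP (2.98-fold and 3.58-fold) and TBP1, the TATA-binding protein (2.36-fold and 2.90-fold). Sucsyn, the sucrose synthase control transcript, was lower by 9.29-fold and 7.36-fold, and XTH by 3.94-fold and 3.46-fold. CAT1 and FBP were dim in both female organs at TET, and XTH in anthers. The additional probe set of FBP did not follow at TET, with 5.59 in anthers, 6.10 in ovaries and 6.18 in stigmas. In all, 2646 probe sets were higher and 2438 lower in anthers than in ovaries, and 3120 and 2234 against stigmas. Stigmas and ovaries were closest here, with 430 higher and 685 lower in stigmas, and none of the 21 named genes called. Anther against stigma split into 1819 higher and 4890 lower, and stigma against ovary into 1014 and 403, with arrays set equal on the hybridisation controls.

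At the uninucleate stage GAPN, FBP, CAT1 and petC showed their largest excess in anthers over both female organs. GAPN, a non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, had a mean of 9.72 ± 0.08 (SD, n = 3) in anthers and 5.36 ± 0.40 (SD, n = 3) in ovaries, a 20.5-fold difference (4.36, SE 0.24, adjusted p = 1.4e-16), and was 35.1-fold higher than in stigmas. GAPN, FBP and CAT1 were dim in both female organs at UNM. FBP was 17.1-fold and 16.8-fold higher, CAT1 10.7-fold and 12.9-fold, and petC 6.88-fold and 24.3-fold. XTH was 5.01-fold and 4.49-fold lower. Between stigmas and ovaries, petC was 3.53-fold lower and CYP86-TA 3.05-fold higher in stigmas, and Sucsyn was 2.06-fold lower, a call that ended with scaling on the brighter probe sets (-0.96) and without stigma UNM replicate 2 (-0.97). Called totals were 3711 higher and 3964 lower for anther against ovary, 4125 and 3661 for anther against stigma, and 677 and 1216 for stigma against ovary. Setting arrays equal on the hybridisation controls made the anther and ovary split 2692 and 7255, and the anther and stigma split 2990 and 7259. Scaling on the brighter probe sets made the anther and ovary split 4189 and 3379.

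At the bicellular stage actin joined the genes higher in anthers. Its mean was 9.56 ± 0.76 (SD, n = 3) in anthers against 6.05 ± 0.15 (SD, n = 3) in ovaries and 6.82 ± 0.03 (SD, n = 3) in stigmas, which made it 11.4-fold (3.51, SE 0.19, adjusted p = 2.8e-17) and 6.67-fold higher. GAPN was 12.9-fold and 18.9-fold higher, FBP 2.91-fold and 2.99-fold, and CAT1 3.48-fold and 5.52-fold; GAPN and CAT1 were dim in both female organs. Lower in anthers were XTH (10.2-fold and 31.7-fold), Sucsyn (5.92-fold and 4.24-fold) and CYP86-TA (3.64-fold and 13.1-fold); the log2 difference of CYP86-TA against ovaries was -1.86, and -1.10 without anther BCP replicate 3. XTH was dim in anthers. TUBA, an alpha-tubulin, was 2.27-fold lower in anthers than in stigmas (-1.18, SE 0.11). Called totals were 3904 higher and 4464 lower for anther against ovary, 4527 and 4465 for anther against stigma, and 1865 and 2354 for stigma against ovary, in which XTH was 3.10-fold and CYP86-TA 3.59-fold higher and petC 3.38-fold lower in stigmas. Under scaling on the hybridisation controls, anther against stigma became 3468 and 6537, and stigma against ovary 2492 and 1833. Scaling on the brighter probe sets made the anther and ovary split 4390 and 3913.

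At the tricellular stage actin reached 13.98 ± 0.04 (SD, n = 3) in anthers, 161-fold above ovaries (7.33, SE 0.19, adjusted p = 8.1e-27) and 114-fold above stigmas. G-6-PDH, higher in anthers at TET, was now 19.1-fold lower there than in ovaries (-4.26, SE 0.21) and 23-fold lower than in stigmas. petC, also higher in anthers at TET, was 8.67-fold lower than in ovaries. SAHH, the adenosylhomocysteinase of the methylation cycle, was 7.67-fold and 5.57-fold lower. Sucsyn was 37.8-fold and 32.2-fold lower. XTH was 22-fold lower than in ovaries and 199-fold lower than in stigmas (-7.64, SE 0.21, adjusted p = 4.3e-26). XTH, G-6-PDH and CYP86-TA were dim in anthers at TCP, with means of 5.36, 5.19 and 4.85, and GAPN and gapdh were dim in both female organs. FBP was 2.86-fold lower in anthers than in stigmas. CYP86-TA was 9.11-fold and 5.59-fold lower at its 3' probe set, while its 5' probe set had means of 7.87 in anthers, 7.28 in ovaries and 7.70 in stigmas. The gapdh control was 3.72-fold and 4.47-fold higher in anthers at its 5' probe set. GAPN was 2.25-fold higher in anthers than in stigmas, a call that ended with arrays set equal on the hybridisation controls (0.64) and without anther TCP replicate 1 (0.96).

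Among the named genes, stigmas at the tricellular stage differed most from ovaries in XTH, which was 9.07-fold higher (3.18, SE 0.21, adjusted p = 9.2e-15), in petC, which was 7.72-fold lower, and in FBP, 3.51-fold higher. Called totals at TCP were 6134 higher and 10103 lower for anther against ovary, 4873 and 9371 for anther against stigma, and 3480 and 4279 for stigma against ovary. The split was sensitive to scaling for anthers: against ovaries it was 11336 higher and 8065 lower with scaling on the brighter probe sets, and 3077 and 15733 with arrays set equal on the hybridisation controls; against stigmas it was 7456 and 7534, and 2856 and 14226. TUBA was called 2.26-fold lower in anthers than in ovaries (-1.18, SE 0.11), a call that ended with scaling on the brighter probe sets (-0.85) and was larger with arrays set equal on the hybridisation controls (-1.81).

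**Figure D2:**
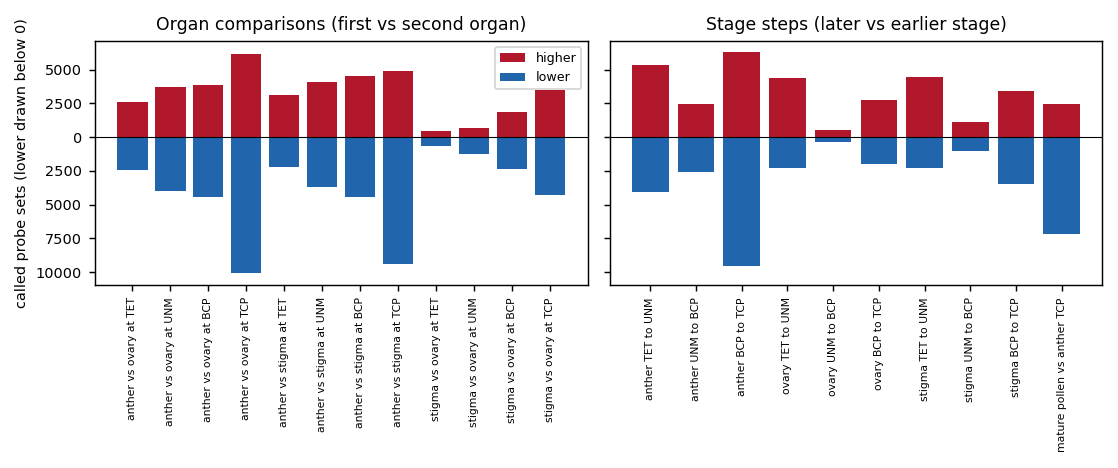
Called probe sets (adjusted p under 0.05 and at least a 2-fold difference), with higher calls drawn up and lower calls drawn down from 0, for organ comparisons by stage on the left and for stage steps and MPG against anther TCP on the right. The tallest bars are the 10103 lower calls of anther against ovary at TCP and the 9537 lower calls of anthers from BCP to TCP; the shortest step is ovary UNM to BCP, with 510 higher and 348 lower.

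From UNM to BCP, the step with unchanged kits, actin rose in anthers and 6 named genes fell. Actin rose 12.2-fold from a dim mean of 5.95 (3.61, SE 0.19, adjusted p = 3.4e-17). Its other probe sets moved the same way, from 4.67 to 12.52 for the 3' segment and from 5.86 to 7.15 for the 5' segment. CYP86-TA fell by 7.69-fold, Sucsyn by 5.43-fold, G-6-PDH by 3.75-fold, petC by 2.80-fold, XTH by 2.28-fold and FBP by 2.27-fold. The calls of petC (-0.94), XTH (-0.64) and FBP (-0.63) ended with arrays set equal on the hybridisation controls, and that of FBP also without anther BCP replicate 3 (-0.89). The 5' and M segment probe sets of CYP86-TA did not follow: their means were 6.77 and 6.95 at UNM and 6.98 and 6.91 at BCP. The 18SrRNA control rose 4.30-fold. Its mean also went from 11.92 to 13.16 in ovaries and from 12.03 to 13.15 in stigmas, where it was not called. The poly-A controls rose in all 3 organs at this step too, and a technical source of the 18SrRNA rise was not tested.

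In stigmas the same step raised XTH 3.09-fold (1.63, SE 0.21, adjusted p = 6.1e-07), from 9.01 ± 0.26 to 10.64 ± 0.48 (SD, n = 3), and FBP 2.47-fold (1.30, SE 0.20); FBP was dim at UNM in stigmas and ovaries. Of the named genes, FBP alone was called in ovaries, up 2.58-fold (1.37, SE 0.20, adjusted p = 4.5e-05). Called totals were 2463 higher and 2611 lower in anthers, 1159 and 1050 in stigmas, and 510 and 348 in ovaries. The ovary total of 858 was 568 without ovary BCP replicate 1. Scaling on the hybridisation controls gave splits of 6741 and 1288 in anthers, 3483 and 460 in stigmas, and 1264 and 145 in ovaries. Across probe sets, which are not independent replicates, changes at this step correlated with r of 0.32 between stigmas and ovaries, 0.03 between anthers and ovaries, and 0.04 between anthers and stigmas.

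From TET to UNM, where the kits also changed, several named genes rose in anthers. GAPN rose 20.1-fold from a dim mean of 5.40 (4.33, SE 0.24, adjusted p = 2.4e-16), Sucsyn 9.9-fold, FBP 8.97-fold, petC 6.39-fold, CYP86-TA 4.31-fold at its 3' probe set and SAHH 3.45-fold. The 5' probe set of Sucsyn did not follow, at 3.96 and 3.51. TBP1 fell by 3.57-fold (-1.84, SE 0.13, adjusted p = 4.8e-14). Several genes rose in the female organs as well: petC 4.35-fold in ovaries and 2.38-fold in stigmas, XTH 2.59-fold and 2.65-fold, G-6-PDH 2.56-fold and 2.40-fold, and SAHH 2.18-fold and 2.92-fold, and CYP86-TA 3.16-fold in stigmas. Under scaling on the hybridisation controls the calls of SAHH ended in anthers, ovaries (0.64) and stigmas (0.74), those of XTH in ovaries (0.88) and stigmas (0.60), and those of G-6-PDH in the same organs (0.87 and 0.46). That scaling also ended the calls of petC (0.45) and CYP86-TA (0.86) in stigmas, and brought CYP86-TA in anthers from 2.11 to 1.32. The call of SAHH in ovaries ended with scaling on the brighter probe sets too (0.90). Called totals were 5371 higher and 4030 lower in anthers, 4395 and 2307 in ovaries, and 4494 and 2248 in stigmas. Of the rises, 3242 were shared by stigmas and ovaries, where independent lists would share 322.7. The changes of stigmas and ovaries correlated with r = 0.84 across probe sets, and those of anthers with r of 0.56 with ovaries and 0.53 with stigmas.

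The direction split at that step depended on scaling. On the hybridisation controls it was 2358 higher and 21495 lower in anthers, 2243 and 8799 in ovaries, and 1433 and 21548 in stigmas. With scaling on the brighter probe sets it was 4633 and 5025 in anthers, 3213 and 4074 in ovaries, and 3419 and 3418 in stigmas.

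From BCP to TCP, the other step with a kit change, many of the named genes fell in anthers. petC fell by 11.2-fold (-3.48, SE 0.21, adjusted p = 3.4e-16), SAHH by 8.44-fold, GAPN by 7.79-fold, G-6-PDH by 6.51-fold, Sucsyn by 5.79-fold, CAT1 by 3.02-fold and FBP by 2.64-fold, while actin rose a further 21.5-fold (4.43, SE 0.19, adjusted p = 2e-20) and gapdh 4.65-fold at its 5' probe set. G-6-PDH and CAT1 were dim in anthers at TCP, and gapdh at BCP. The fall of Sucsyn was at its 3' probe set alone: its M probe set had means of 5.54 and 6.11, and its 5' probe set 3.39 and 4.22. The additional probe set of FBP rose, from 4.50 to 6.36. The size of the actin rise depended on the probe set: the 3' probe set went from 12.52 to 13.96 and the 5' probe set from 7.15 to 13.55. In stigmas XTH rose 5.14-fold (2.36, SE 0.21, adjusted p = 2.9e-11) and FBP 3.25-fold, and petC fell by 2.25-fold and CYP86-TA by 6.92-fold at its 3' probe set, while its 5' probe set had means of 7.18 and 7.70. In ovaries the called named genes were gapdh, up 2.13-fold but dim at both stages, and 18SrRNA. The gapdh call ended without ovary BCP replicate 3 (0.86). The 18SrRNA control fell by a log2 difference of 7.78 in ovaries, 7.23 in stigmas and 4.35 in anthers, and its SD over the 3 anther TCP arrays was 2.40. Called totals were 6329 higher and 9537 lower in anthers, 2793 and 1950 in ovaries, and 3402 and 3474 in stigmas. Without the 2-fold minimum the majority in anthers turned, with 22121 higher and 15120 lower. In anthers the split was 10456 and 7738 with scaling on the brighter probe sets; with arrays set equal on the hybridisation controls it was 4273 and 11413 in anthers and 4168 and 881 in ovaries.

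**Figure D3:**
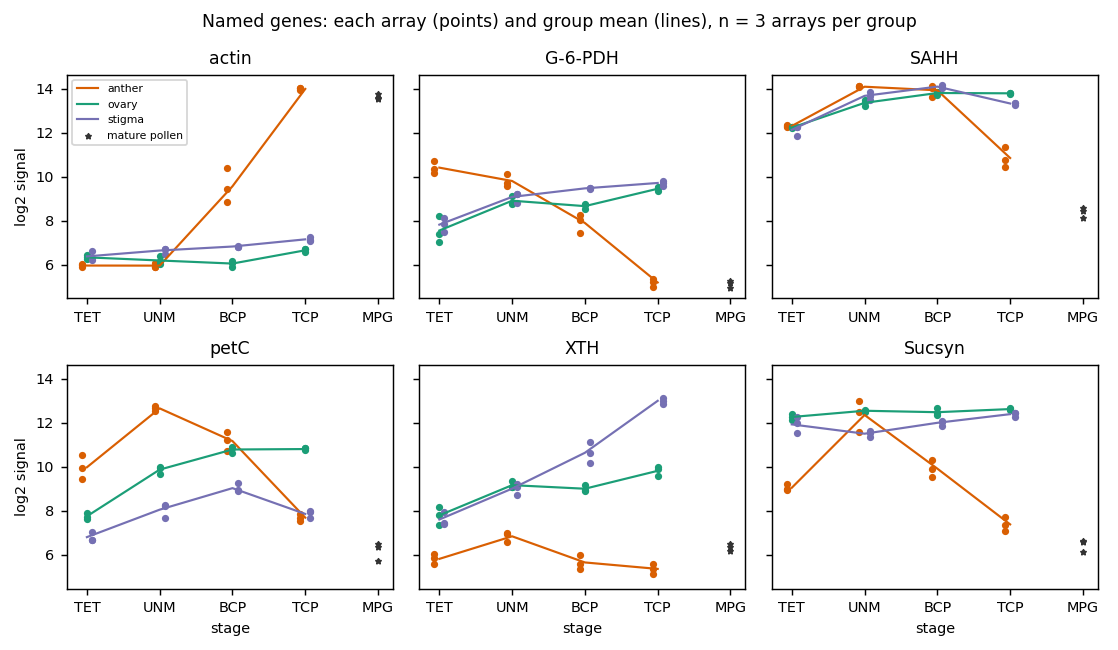
Log2 signal of 6 named genes by stage, with a point for each array, lines through the group means of anthers, ovaries and stigmas, and stars for MPG (n = 3 arrays per group). The group mean of actin climbs in anthers from 5.95 at UNM to 13.98 at TCP and stays at or below 7.15 in the female organs. That of XTH climbs in stigmas from 7.60 at TET through 9.01 and 10.64 to its highest level at TCP. The means of G-6-PDH, SAHH, petC and Sucsyn end lower in anther TCP than in ovary TCP.

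Mature pollen was compared with anthers at TCP, which still hold tricellular pollen, under matched kits but with poly-A controls at 9.02 against 5.90. Pollen held less SAHH (5.53-fold lower, -2.47, SE 0.15, adjusted p = 1.1e-15), less petC (2.85-fold lower) and less FBP (2.32-fold lower), and no named gene was called higher. Actin was at 13.61 ± 0.12 (SD, n = 3) in pollen and 13.98 ± 0.04 (SD, n = 3) in the anthers. Over all probe sets 2436 were higher and 7186 lower in pollen, and 19 of the higher and 1515 of the lower differed by at least 8-fold. Without the 2-fold minimum the majority turned, with 20481 higher and 11742 lower. The splits that follow keep that minimum. The split was 5262 and 6142 with scaling on the brighter probe sets and 803 and 9341 with arrays set equal on the hybridisation controls, and among probe sets with a mean of at least 8 in either group, a limit set after seeing the data, it was 782 and 3591.

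Pollen-associated probe sets, called higher in mature pollen than in both ovaries and stigmas at TCP, included actin, 125-fold and 88.3-fold higher, the gapdh control, 4.62-fold and 5.55-fold higher, and 18SrRNA. The gapdh value came from its 5' probe set; its 3' probe set stayed dim, with 4.58 in anther TCP as the highest mean in an organ. Against the same organs pollen held less Sucsyn (73-fold and 62.2-fold), SAHH (42.4-fold and 30.8-fold), G-6-PDH (20.1-fold and 24.1-fold), XTH (11.2-fold and 101-fold) and TUBA (3.89-fold and 3.03-fold). G-6-PDH was dim in pollen, and gapdh and 18SrRNA were dim in both organs. The 18SrRNA mean was 7.69 in pollen and 8.84 in anther TCP, with an SD of 2.40 in the latter. Whether its signal follows transcript abundance was not tested. The set held 9100 probe sets, of which 72.7% had a mean under 8 in pollen. It shrank to 1975 with arrays set equal on the hybridisation controls, which moves all probe sets alike by -0.60 in MPG, 0.35 in ovary TCP and 0.25 in stigma TCP, grew to 19816 with scaling on the brighter probe sets, and was 5346 when only the brighter 50% of probe sets were tested.

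The 2480 pollen-associated probe sets with a mean of at least 8 in pollen, a limit set after seeing the data, traced the rise of this set in anthers. Their medians there were 6.72 at TET, 6.83 at UNM, 7.35 at BCP and 9.26 at TCP, against 9.74 in MPG, 6.75 in ovary TCP and 6.87 in stigma TCP. From UNM to BCP, 24.4% of them rose in anthers and 2.7% fell. From BCP to TCP, a step that crosses a kit change, 65.1% rose and 2.5% fell. Over all 61204 probe sets, 2463 rose and 2611 fell at the earlier step, and 6329 rose and 9537 fell at the later. Of all anther rises from UNM to BCP, 855 were pollen-associated, where independent lists would share 366.2, and of the falls 151, against 388.2. The group means compared share no arrays, but each probe set's variance was estimated over all arrays and enters both lists. Independent lists are therefore not a clean baseline. Anther rises from UNM to BCP also exceeded that baseline with stigma rises (144 against 46.6) and with stigma falls (145 against 42.3) at the same step. The contrast of anther rises with anther falls is descriptive and was not tested.

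The change from TET to TCP differed between organs, which was tested as an interaction; a kit effect equal in both organs on the log2 scale cancels there. Among the named genes, it differed most between anthers and ovaries in actin (7.71, SE 0.27, adjusted p = 1.7e-22), G-6-PDH (-7.12, SE 0.30) and petC (-5.34, SE 0.30). Between anthers and stigmas the largest differences of named genes were in actin (7.25, SE 0.27), G-6-PDH (-7.11, SE 0.30) and XTH (-5.85, SE 0.29). Between stigmas and ovaries, XTH (3.37, SE 0.29, adjusted p = 4.3e-11) and FBP (2.07, SE 0.29) gained more in stigmas, and petC (-2.00, SE 0.30) gained more in ovaries. Called totals were 6835 higher and 10095 lower for anthers against ovaries, 6082 and 10134 for anthers against stigmas, and 3719 and 3714 for stigmas against ovaries. With scaling on the brighter probe sets the splits with anthers were 12398 and 8118, and 10241 and 8229. On the hybridisation controls they were 3161 and 15077 for anthers against ovaries, and stigmas against ovaries gave 2090 and 7425.

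Each scaling shifted the median log2 difference of all probe sets, and the differences above can be read relative to these shifts. On the hybridisation controls the shift over 4 stages was -0.29 for anther against ovary, -0.40 for anther against stigma and 0.11 for stigma against ovary. Within stages, anther against ovary shifted by -0.35 at UNM, -0.12 at BCP and -0.63 at TCP, anther against stigma by -0.41, -0.40, -0.27 and -0.54 from TET to TCP, and stigma against ovary by 0.36 at TET and 0.15 at BCP. From TET to UNM the shift was -0.78 in anthers, -0.49 in ovaries and -0.80 in stigmas, from UNM to BCP 0.55, 0.31 and 0.43, and from BCP to TCP -0.24 in anthers and 0.27 in ovaries. For mature pollen against anther TCP it was -0.32, and for the interactions -0.57, -0.12 and -0.45. On the brighter probe sets, shifts over 0.1 were 0.14 for anther against ovary over 4 stages, 0.11 at UNM and 0.32 at TCP, 0.25 for anther against stigma at TCP, -0.13, -0.22 and -0.18 from TET to UNM in anthers, ovaries and stigmas, 0.27 from BCP to TCP in anthers, 0.19 for mature pollen against anther TCP, and 0.31 and 0.27 for the interactions of anthers with ovaries and with stigmas.

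Probe sets of the same gene did not always move together. For Sucsyn, the 3' probe set stayed at 12.48 and 12.62 in ovaries at BCP and TCP, while the M probe set went from 7.92 to 10.92 and the 5' probe set from 3.98 to 8.03. For G-6-PDH in ovaries the 3' probe set went from 8.66 to 9.45 and the 5' probe set from 4.17 to 7.94. The additional probe sets of CAT1, petC and TUBA were dim, with means of at most 4.90, 3.84 and 5.18. That of FBP reached 6.90 in MPG, above its 6.36 in anther TCP and 5.50 in stigma TCP. In anthers it fell from 5.59 at TET to 4.65 at UNM, where ovaries had 4.60 and stigmas 4.67. From TET to TCP it fell from 6.10 to 5.27 in ovaries and from 6.18 to 5.50 in stigmas. Statements on FBP therefore stand only for its representative probe set. The probe sets of SAHH moved alike. COR410, PFK, THI1.1, THI1.2, TTHV and ef1a had no group mean of 6 or more, and are not interpreted.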

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

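The tests of splits, of the bright pollen-associated probe sets and of pollen RNA in stigma samples were set out before their results were seen; the other tests were chosen after the patterns were seen. The test of the make-up of the stigma shift (69.4%) was added after the result of the pollen RNA test (0.66) was known, and its threshold was written before its own value was computed.

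The change from TET to TCP differed between organs by a test of the difference itself. It was called at 16930 probe sets for anthers against ovaries, 16216 for anthers against stigmas and 7433 for stigmas against ovaries. The 2 largest differences per direction among named genes are given here. Between anthers and ovaries they were actin (7.71, SE 0.27), 18SrRNA (3.23, SE 0.73; 1.89 without anther TCP replicate 3), petC (-5.34, SE 0.30) and G-6-PDH (-7.12, SE 0.30). Between anthers and stigmas they were actin (7.25, SE 0.27), 18SrRNA (2.52, SE 0.73; 1.18 without anther TCP replicate 3, and adjusted p = 0.056 with only the groups compared in the fit, the highest of its alternatives, whose lowest was 8e-06), XTH (-5.85, SE 0.29) and G-6-PDH (-7.11, SE 0.30). Between stigmas and ovaries they were XTH (3.37, SE 0.29), FBP (2.07, SE 0.29), CYP86-TA (-1.47, SE 0.46; adjusted p = 0.018, and 0.06 without ovary TET replicate 3, the highest of its alternatives, whose lowest was 0.00015) and petC (-2.00, SE 0.30).

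More probe sets were called in ovaries and stigmas at steps with a kit change than from UNM to BCP. For the shared part, stigma and ovary changes from TET to UNM correlated with r = 0.84 across probe sets; a kit change that acts alike on every organ and a shared change of stage cannot be told apart there, since the design ties them. The interaction of stigmas against ovaries from TET to TCP called 7433 probe sets. A kit effect equal in both organs on the log2 scale cancels there, but such equality was not tested. The interaction also spans UNM to BCP, where kits did not change and 2209 probe sets were called in stigmas and 858 in ovaries. It therefore does not isolate the part of the kit steps that differs between these organs. An effect of kits on the ends of transcripts may contribute to the larger counts at the kit steps. Over 3 control transcripts and 3 organs, the size of the change in 3' minus 5' had a median of 1.73 at the kit steps. From UNM to BCP the median was 0.26, although anthers changed by -2.32 (Sucsyn) and -1.48 (G-6-PDH) there without a kit change. The 5' probe sets of Sucsyn and G-6-PDH were dim in every organ at TET, UNM and BCP. There the measure can follow the 3' probe set alone and cannot show an effect on the ends. Ubiquitin, not dim at either end, changed by -1.63, -1.86 and -1.82 from TET to UNM in anthers, ovaries and stigmas. It changed by -0.26, 0.64 and -0.15 from UNM to BCP, and by -0.53, -0.84 and -0.64 from BCP to TCP. Stage changes at the kit steps, so a kit effect on the ends stays open. A kit or RNA input effect that differs between organs (poly-A controls at 8.61 in ovary TCP and 5.85 in stigma TCP) and development itself stay open too.

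Of the 9100 pollen-associated probe sets, 72.7% had a mean under 8 in pollen. At the 2-fold minimum, though not without it (20481 higher and 11742 lower), mature pollen had more lower than higher calls against anther TCP. A normalization to like distributions, which lifts dim probe sets on arrays with few bright ones, may contribute to both, but the tests made of it decide nothing. Setting arrays equal on the hybridisation controls moves all probe sets of an array alike (-0.60 in MPG, 0.35 in ovary TCP, 0.25 in stigma TCP), so it does not separate dim from bright, and the bounds written for it were wrong, the one set out before its result included. Under it the pollen-associated count had to fall, to 1975, lower calls against anther TCP had to rise, from 7186 to 9341, and 58.4% of the 2480 members with a mean of at least 8 in pollen were still called. The normalization, a difference in RNA input and, as a biological hypothesis, a narrower set of transcripts in pollen all stay open.

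Stigma TCP arrays lay nearer the pollen side of the first component than stigma BCP arrays, by 76.3, while ovaries moved by 39.4. A kit effect equal in both organs on the log2 scale leaves the difference of 36.9 (SD 12.7) unexplained, but such equality was not tested. RNA of pollen grains in the stigma TCP samples may be present. This was tested on 96 probe sets with a mean of at least 13 in pollen and at most 5 in ovary TCP. They rose by a median of 0.66 from stigma BCP to TCP (bootstrap interval 0.50 to 0.84 over probe sets, which leaves out the spread between samples). The median levels of 4.01 and 4.71 are both dim, so no share of pollen RNA is estimated. The level in ovary TCP (4.07) is low by the choice of the probe sets. The rise also crosses the kit change, and the change of these probe sets in ovaries is not given. The make-up of the shift does not decide whether pollen RNA caused the whole 76.3. Of the shift, 69.4% came from probe sets no higher in pollen than in stigma BCP. These were chosen by the stigma BCP mean that the change also uses, which can favour a large share. The make-up of the ovary shift is not given for comparison. The make-up of the 36.9 beyond ovaries was not tested. Pollen RNA stays open as a cause of the whole shift and of the 36.9. Maturation of the stigma stays open and was not tested.

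Other splits of the arrays bear on chance. For the organ comparisons over 4 stages, labels were redrawn within stages 100 times, the real split included, and 1 of 100 reached the real count in each: 7534 against a highest other of 3429 (anther and ovary), 6968 against 3936 (anther and stigma) and 2471 against 946 (stigma and ovary). The same held for the sets, with 2533 against 1201 for anthers, 835 against 685 for ovaries, 594 against 450 for stigmas and 9100 against 5114 for pollen. A share of 1 of 100 is the lowest these splits allow, so they bound chance no further. A redraw also puts arrays of different tissues into a group, which widens the spread and lowers the calls. For the interactions, 2 of 100 splits reached 16930 (highest other 18478), 1 reached 16216 (highest other 14949) and 7 reached 7433 (highest other 9048), but these splits decide nothing about chance. Exchanging the organs at a single stage turns a difference of changes into a sum of organ differences, and all 6 other splits that reached 7433 kept or fully exchanged the organs at TCP. The share of 0.05 written for them was therefore the wrong bound, and the interactions rest on their own test.

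Comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05; in each, 1 split, the real one, reached the real count. Highest other counts for anther and ovary, anther and stigma, and stigma and ovary were 86, 1 and 7 at TET (real 5084, 5354 and 1115), 19, 3 and 28 at UNM (7675, 7786 and 1893), 0, 94 and 405 at BCP (8368, 8992 and 4219) and 0, 5 and 1 at TCP (16237, 14244 and 7759). For TET to UNM, UNM to BCP and BCP to TCP they were 54, 152 and 36 in anthers (9401, 5074 and 15866), 2, 52 and 1 in ovaries (6702, 858 and 4743) and 16, 196 and 6 in stigmas (6742, 2209 and 6876), and 252 for mature pollen against anther TCP (9622).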

How the results depend on the processing

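The mean of UNM and BCP alone and the minimum mean of 8 were tests chosen only after the data were seen. Of the 32 counts of called probe sets, all stayed within 1.5 times under the fit on the compared groups alone (ratios 0.856 to 1.01), the variance trend (0.941 to 1), array weights (0.976 to 1.11), the threshold of 0.01 (0.787 to 1) and the replicate block (0.999 to 1.01; for the pairs that the pairing check bore out, anther against stigma at BCP, 8992 with and without the block). Elsewhere the samples share only a number: over 22 pairs of groups the correlation of same-numbered arrays had a median of 0.009 and ran from -0.195 to 0.436, and the block changed no call of a named gene. With arrays set equal on the hybridisation controls, 7 counts moved: 23853 for TET to UNM in anthers, 11042 in ovaries and 22981 in stigmas, 8029 for UNM to BCP in anthers, 1409 in ovaries and 3943 in stigmas, and 1975 pollen-associated. Scaling on the brighter probe sets moved the pollen-associated count to 19816, and testing only the brighter 50% moved it to 5346; the latter tests fewer probe sets. The splits moved by over 10 percentage points in 22 counts under scaling on the hybridisation controls and 8 under scaling on the brighter probe sets. They also did in 5 of the 7 counts run without a minimum fold. Both scalings move all probe sets of an array alike, so the log2 differences of a comparison shift together and the splits move with them. From TET to UNM in anthers the shift on the hybridisation controls was -0.78, and lower calls went from 4030 to 21495. Why the arrays differ in these controls, and the cause of the moves without a minimum fold, were not tested. Without a minimum fold, which by construction admits smaller differences, the counts were 32332 (anther and ovary), 28821 (anther and stigma) and 18492 (stigma and ovary) over 4 stages, 24601, 13150 and 37241 for the successive anther steps, and 32223 for mature pollen against anther TCP. The splits that moved were 16985 higher and 15347 lower (anther and ovary) and 9170 and 9322 (stigma and ovary). In anthers they were 11121 and 13480 from TET to UNM and 22121 and 15120 from BCP to TCP. For mature pollen the split was 20481 and 11742. With a mean of at least 8 in a compared group, mature pollen against anther TCP gave 4373 and the pollen-associated set 2480, the latter also with that limit in pollen alone; fewer probe sets are tested there. The mean of UNM and BCP alone gave ratios of 0.76 to 1.19. Leaving out each array in turn kept 356 of 357 counts within 1.5 times, with ratios of 0.662 to 1.23. The exception was UNM to BCP in ovaries, 858 in full, which ran from 568 without ovary BCP replicate 1 to 1053 without ovary UNM replicate 3.

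Named genes were called in 171 pairs of gene and comparison; no pair changed direction under any alternative, and 140 kept their call under all that were run. With arrays set equal on the hybridisation controls 18 calls were lost and 153 kept, and with scaling on the brighter probe sets 9 and 162. Over the refits that left out an array, 23 were lost and 1489 kept. The mean of UNM and BCP alone, which applied to fewer pairs, lost 3 and kept 14. The list tests, with their estimated correlation and with all probe sets of a list, were not run, because no list had 5 named members. Signal over background limits dim probe sets: 6 of the 21 named genes had no group mean of 6 or more.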

Other observations

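At the step without a kit change, stigmas and ovaries shared more calls than independent lists would. Of the rises from UNM to BCP, 137 were shared against 9.7 expected, which is 11.8% of the stigma rises and 26.9% of the ovary rises, and of the falls 138 against 6; rises in stigmas that fell in ovaries numbered 4, against 6.6. Anther rises from UNM to BCP overlapped with stigma rises (144 against 46.6) and with stigma falls (145 against 42.3) alike.

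Anther BCP replicates differed in actin, at 9.449, 8.858 and 10.371, and on the first component, at 29.7, 24.1 and 66.6; the replicate with the highest actin also had the highest score. The 18SrRNA control had a mean of 8.84 and an SD of 2.40 in anther TCP, against SDs of at most 0.36 in every other group. ef1a, a control often taken as abundant, had means of 5.08 to 5.91 at its brightest probe set. The ubiquitin 3' minus 5' difference was above 0 in all 3 TET groups (0.56, 0.17 and 0.41) and below 0 in every other group.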
